A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

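Gene expression was measured in budding yeast (Saccharomyces cerevisiae) of the wild-type strain W1588-4c. Cultures in YPD, a rich glucose medium, were taken at log phase (OD600 0.6 to 0.8) and given ebselen, a selenium-containing drug that reacts with thiols, at 100 µM for 3 h, or its solvent DMSO, per the labels' protocols. Each group had 2 arrays, which the labels call biological replicates. RNA was labelled with biotin from its poly-A end (3′ IVT Express chemistry) and hybridized to Affymetrix GeneChip Yeast Genome 2.0 arrays, per the labels' protocols and the design text. This array type also carries probe sets for fission yeast (Schizosaccharomyces pombe), which served here as a background.

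The authors normalized the scanner files with RMA, per the submitters' processing notes, and used a trial copy of GeneSpring 7.2 and a t-test with Benjamini-Hochberg correction, per the design text. The deposited values are on a log scale, taken here as log2. The base of the logarithm is not given in the sources used here; log2 was assumed because RMA gives log2 values, and every fold change rests on that assumption. In the deposited table the median of each probe set over the 4 arrays was 0 (largest absolute median 5e-07). A value is therefore a level relative to the probe set's own median, absolute levels are unknown, and arrays of opposite groups correlate negatively by construction. Scanner files were not used here.

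Of 10928 probe sets, 7244 had 1 gene symbol in the platform annotation, 1 had several and 3683 had none, of which 166 were control probe sets. Matching to a RefSeq gene table of assembly R64, used for names, gene neighbours and coding lengths, placed 5498 probe sets on 5449 S. cerevisiae genes and updated 12 symbols. Another 1747 annotated probe sets were outside that table and were taken as S. pombe probe sets. Coding length ran from start to stop codon with introns included. The files name no genome build, so no coordinates are given. The brightest probe set was to stand for each of the 47 genes with more than 1, but brightness is not kept in centred values, and the mean of a gene's probe sets was used instead. Probe sets with no listed gene, other than controls, were also to stay in the fit, but only the 5449 genes were fitted. With all probe sets except controls in one fit, including those of S. pombe, 1504 genes were called higher and 1763 lower, against 1796 and 2113.

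The arrays labelled ebselen were compared with the DMSO arrays in limma 3.58.1 (R 4.3.3), with lmFit and eBayes, group as the only term, two-sided tests and Benjamini-Hochberg adjustment over the 5449 genes at a threshold of 0.05. The residual degrees of freedom were 2 and the prior ones 3.13. A total of 45 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and limma's fry were run beside it. Each list's median was also set against 10000 random lists of the same size matched on coding length. Apart from the changes in probe sets given above, the groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names the 12 genes with the largest rise and the 12 with the largest fall among genes past the test with both ebselen arrays on one side of both DMSO arrays. For each list past the set test, it also names the 3 members with the largest change in the direction of the list's median. Up to 2 members past the gene test are named in the other lists, and 12 regulators and glutamate dehydrogenases were fixed by name. Genes named outside the rule are marked as chosen after their values were seen. Figures were drawn with matplotlib 3.10.9.

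The procedure was tested on simulated data with 200 changed genes among the 5449 of this comparison, in 20 draws. It recovered 11.9% of genes changed by 0.3 on the log2 scale, 75% at 0.5, 96.8% at 1 and 99.4% at 2, with 5.56% false genes among its calls. A shift of −0.3 in the proteasome list was recovered in 20 of 20 draws with 0 other lists called. Simulated genes varied independently of each other, whereas the correlation estimated in the data was 0.158 for the proteasome list. Over all lists it ran from −0.11 to 0.58. Far more genes were called in the data (71.7%) than were changed in the simulation. The draws therefore do not give the error rates of the calls reported here. The number of arrays limits the precision of every value.

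Alternatives were the replicate number as a block, each array left out, quantile normalization of the centred values, median centring, all probe sets in one fit, stricter and looser thresholds and the methods' t-test. Chosen after seeing the data were centring on the S. pombe probe sets, scaling on the hybridization controls (bacterial and phage transcripts added to the hybridization mix), removal of the trend with coding length, robust eBayes, 1 probe set per gene, and a minimum change set by the S. pombe probe sets. A filter on dim probe sets, an intensity trend in eBayes and the brightest probe set per gene were not run, because the centred values hold no intensity.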

Results

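The data set described transcript levels of wild-type yeast taken at log phase and given 100 µM ebselen for 3 h (2 arrays) or DMSO (2 arrays). The sample records used here give an exposure time for ebselen only. The comparison asked which genes differ in expression during ebselen treatment. Values were log2 expression relative to each gene's median over the 4 arrays, for 5449 S. cerevisiae genes. Below, rose and fell mean higher and lower in the arrays labelled ebselen, and every direction rests on the deposited labels. Changes are log2 differences with limma's moderated standard errors (SE, n = 2 arrays per group). These combine the spread of a gene's own arrays with a prior SD of 0.063 estimated over all genes. An SE can therefore be larger or smaller than the replicates of that gene alone would give. It is smaller for genes whose replicates vary more than that prior, such as ANB1 (SE 0.17, with SDs of 0.35 in DMSO and 0.12 in ebselen). Arrays of one group resembled each other: the SD over genes of the difference between them was 0.116 for DMSO and 0.143 for ebselen, against 0.726 to 0.731 between arrays of different groups.

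In the arrays labelled ebselen, most genes of cytosolic ribosomal proteins and of entry into S phase rose, while most genes of oxidative stress defence, general stress, stationary phase and respiratory carbon use fell. Of 45 gene lists, limma's camera with Benjamini-Hochberg adjustment placed 9 higher and 21 lower than the other genes at its preset correlation, and 0 lists passed with an estimated correlation (2 higher and 6 lower at an unadjusted p under 0.05). In limma with Benjamini-Hochberg adjustment, 1796 genes rose and 2113 fell, together 71.7% of those tested, and 1540 did not pass. Most changes were small: 228 genes rose and 412 fell by at least 2-fold, 20 rose and 93 fell by at least 4-fold, and the smallest called change was 0.14. Both ebselen arrays lay on one side of both DMSO arrays for 86.6% of genes, against 42.5% of the S. pombe background probe sets, where chance gives 33.3%. These S. pombe probe sets changed by up to 0.60 at their 99th percentile, and 685 rises and 962 falls of S. cerevisiae genes were larger than that. Scaling the arrays on their hybridization controls moved the median change of all genes by −0.48, and the calls then split into 414 rises and 3620 falls (10.3% rises, against 45.9% as deposited), so changes are to be read relative to the typical gene of the array.

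The array's control probe sets showed a difference between the groups in 5′ against 3′ signal. It lies between the same arrays as every gene change described here, so the design cannot separate it from those changes. For 8 yeast transcripts probed at both ends, the 5′ probe set was lower against the 3′ probe set in the arrays labelled ebselen, with a mean change of −0.75 ± 0.26 (SD over 8 transcripts). All 8 were negative, with no overlap between the arrays of the groups (two-sided exact sign-flip test, p = 0.0078, the smallest that 8 transcripts allow, although transcripts of the same arrays are not independent replicates). The 4 poly-A spike-ins, bacterial transcripts added to the RNA before labelling, changed by 0.33 ± 0.38 in the same measure. For ACT1, the actin gene, the 5′ probe set changed by −0.41 and the 3′ probe set by −0.05.

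**Figure D1:**
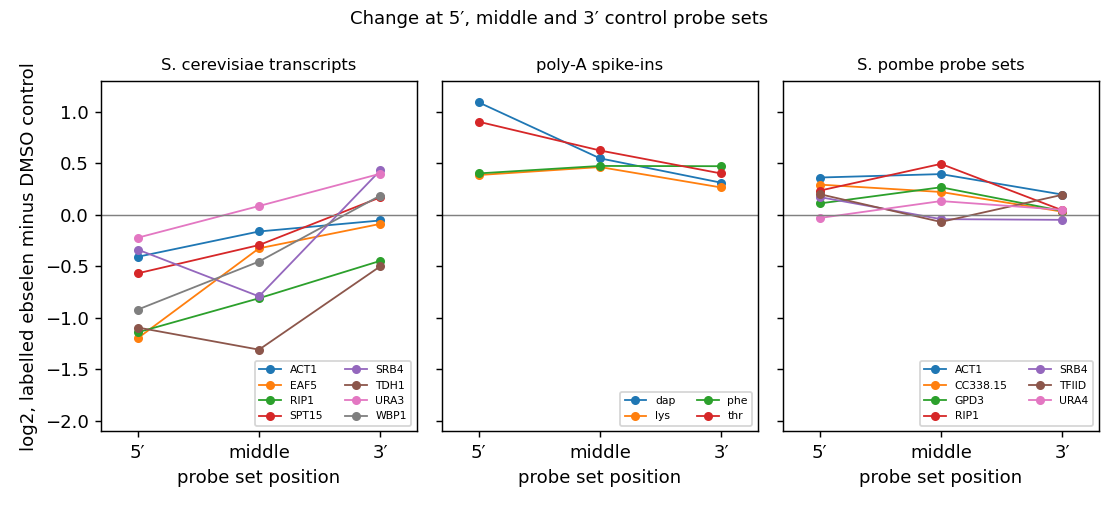
Change in log2 expression (labelled ebselen minus DMSO control, vertical axis) at 5′, middle and 3′ control probe sets (horizontal axis); each line is 1 transcript. In the 8 S. cerevisiae transcripts the 5′ end lies below the 3′ end (mean difference −0.75); in the 4 poly-A spike-ins the mean difference is 0.33.

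Cytosolic ribosomal protein genes rose almost without exception: 128 of 129 measured members passed the test (128 also when adjusted over the list alone), with a median change of 0.92, or 1.89-fold. RPS9A (YPL081W, a small-subunit protein) rose 8.38-fold (3.07 ± 0.057), RPS22B (YLR367W) 5.71-fold (2.51 ± 0.055) and RPL8A (YHL033C, a large-subunit protein) 4.61-fold (2.20 ± 0.071, partly on a shared probe set), each with a limma adjusted p after Benjamini-Hochberg of at most 2.55e-05. RPL10, named after its value was seen, was the member that did not pass (−0.11 ± 0.050). The list was drawn by a name pattern that also takes in RPP1, a subunit of RNase P named after its value was seen (0.43 ± 0.050), and without it 127 of 128 members rose. The list's limma camera adjusted p (Benjamini-Hochberg) was 2.04e-27, and its adjusted p = 0.267 with an estimated correlation. Many ribosomal proteins are encoded by near-identical gene pairs; for 29 of these genes a probe set is marked as shared with other transcripts, and single paralogs are uncertain. With scaling on the hybridization controls 85 members rose and 2 fell, with a median of 0.43.

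All 35 measured genes of the G1/S transition rose (35 adjusted over the list alone), with a median of 1.52, or 2.86-fold. Among them were CLB6 (YGR109C, an S-phase cyclin, 2.39 ± 0.058), GIC2 (YDR309C, an effector of the polarity GTPase Cdc42, 2.31 ± 0.095) and POL1 (YNL102W, the catalytic subunit of DNA polymerase alpha, 2.21 ± 0.099). By limma's camera the adjusted p (Benjamini-Hochberg) was 4.02e-13, and adjusted p = 0.267 with an estimated correlation. On hybridization-control scaling 29 members rose. NRM1 (2.27 ± 0.086), a co-repressor of G1/S genes, was also among the 12 largest rises, which further held FET3 (YMR058W, the ferroxidase of high-affinity iron uptake, 2.75 ± 0.050), HXT2 (a glucose transporter, 2.34 ± 0.057), SFG1 (a putative transcription factor, 2.12 ± 0.073) and the small reading frames YMR230W-A (2.73 ± 0.16) and YMR001C-A (2.36 ± 0.16).

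**Figure D2:**
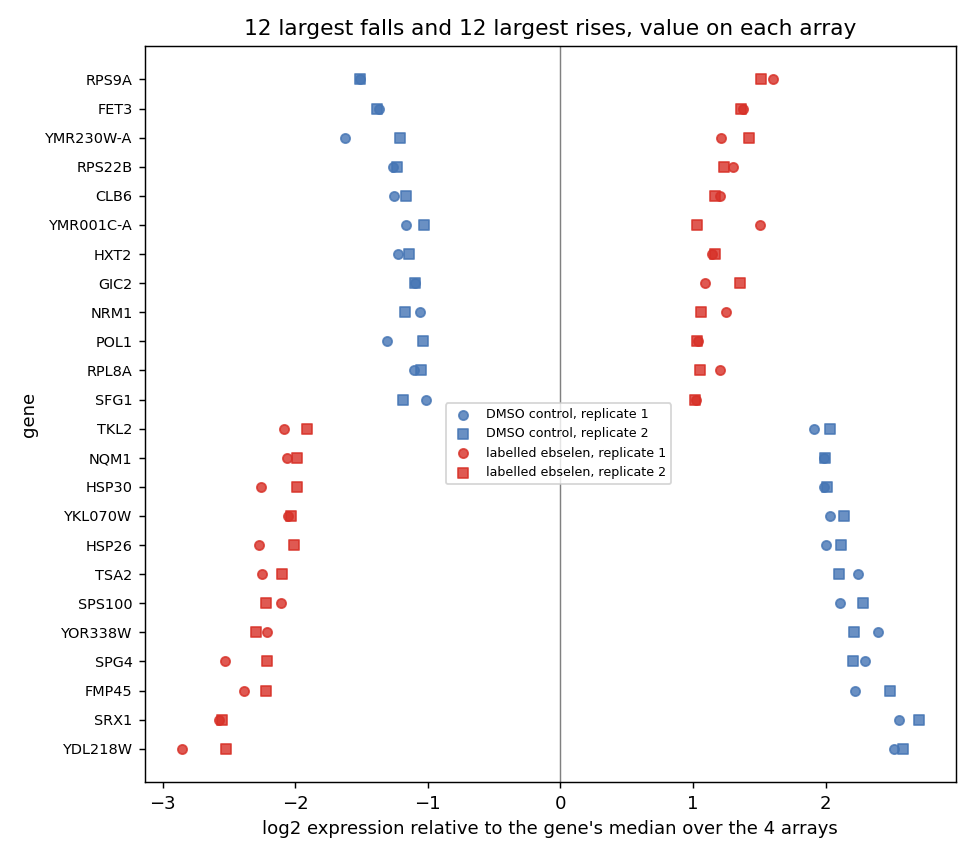
Log2 expression relative to the gene's median over the 4 arrays (horizontal axis) for the 12 largest falls and 12 largest rises (vertical axis); each point is 1 array, coloured by group. Arrays of opposite groups do not overlap for any of the 24 genes, because the rule that chose them required it. Their changes run from YDL218W (−5.24) to RPS9A (3.07).

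Genes of the oxidative stress response fell in the same arrays, where the 8 yeast control transcripts had a mean change of −0.75 for 5′ minus 3′. Whether that lower 5′ signal bears on these genes was not tested. Of 22 measured targets of Yap1, the activator of the peroxide and thiol stress response, 21 fell (22 adjusted over the list alone) and 0 rose, with a median of −0.90. SRX1 (YKL086W, sulfiredoxin, which repairs over-oxidized peroxiredoxins) was 36.5-fold lower (−5.19 ± 0.068), FRM2 (a nitroreductase family member) 14.5-fold (−3.86 ± 0.051) and OYE3 (an NADPH oxidoreductase) 9.62-fold (−3.27 ± 0.075). TRR1, thioredoxin reductase, named after its value was seen, was the member that missed the test (−0.14). Of 30 thioredoxin, peroxiredoxin, glutaredoxin and related antioxidant genes 25 fell (26 adjusted over the list alone), with a median of −0.60, among them the peroxiredoxin TSA2 (YDR453C, −4.35 ± 0.080) and the catalase CTT1 (−2.86 ± 0.095). A list of aldehyde and aryl-alcohol reductases, other NADPH oxidoreductases and related genes fell for 25 of 26 members (25 adjusted over the list alone), with a median of −0.91. Its largest falls besides OYE3 were BDH2 (a putative alcohol dehydrogenase, −3.38 ± 0.077) and SNO4 (a relative of the chaperone HSP31, −2.84 ± 0.11, on a probe set shared with related genes). Adjusted p values of limma's camera (Benjamini-Hochberg) were 2.41e-07 for the Yap1 list, 4.74e-06 for the antioxidant genes and 3.66e-08 for the reductase list, and adjusted p = 0.296, 0.267 and 0.267 with an estimated correlation. The Yap1 list shares 7 genes with the antioxidant list, 5 with the reductase list and 5 with the glutathione list. Lists described below overlap as well. General stress shares 10 genes with the trehalose and glycogen list and 4 with stationary phase. Heat shock shares 3 with stationary phase, and glutamate metabolism shares 8 with the nitrogen catabolite list.

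Glutathione and sulfur genes fell as well. Of 22 glutathione genes 16 fell and 2 rose (16 and 2 adjusted over the list alone, 1 rise without DMSO control replicate 1 or ebselen replicate 2), with a median of −0.55, led by the glutathione transferases ECM4 (−2.50 ± 0.059), GTT2 (−2.19 ± 0.079) and GTO1 (−2.09 ± 0.066). DUG2 (0.66) and OPT1 (0.26), named after their values were seen, were the members that rose. Of 28 genes of sulfate assimilation and methionine synthesis 23 fell and 3 rose (23 and 4 adjusted over the list alone), with a median of −0.62, among them SUL1 (a sulfate transporter, −2.13 ± 0.12), MET3 (ATP sulfurylase, −1.76 ± 0.050) and JLP1 (a sulfonate dioxygenase, −1.72 ± 0.069). MHT1 (0.91), MMP1 (0.49) and MET13 (0.49), named after their values were seen, were the 3 that rose. In limma's camera the adjusted p (Benjamini-Hochberg) was 0.00273 for glutathione and 0.000277 for sulfur genes, and adjusted p = 0.267 for each with an estimated correlation.

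General stress and stationary-phase genes had the lowest medians among the lists. Stationary-phase markers fell for 22 of 23 members (22 adjusted over the list alone), with a median of −2.15, or 4.45-fold, for example FMP45 (YDL222C, a membrane protein, −4.66 ± 0.11), SPG4 (YMR107W, −4.62 ± 0.11) and HSP26 (YBR072W, a small heat shock protein, −4.20 ± 0.10). Of 38 stress genes induced through Msn2 and Msn4, 33 fell and 1 rose (34 and 1 adjusted over the list alone), with a median of −1.22, for example GRE1 (a hydrophilin, −3.54 ± 0.075), SPI1 (a cell wall protein, −3.51 ± 0.11) and RTN2 (−3.05 ± 0.056). The one that rose was GSY1, a glycogen synthase (1.42), named after its value was seen. The limma camera adjusted p (Benjamini-Hochberg) was 4.04e-08 and 3.46e-09 for these lists, and adjusted p = 0.267 and 0.328 with an estimated correlation. YDL218W (37.7-fold, −5.24 ± 0.12), YOR338W (−4.56 ± 0.080), YKL070W (−4.13 ± 0.059), HSP30 (a plasma membrane heat shock protein, −4.12 ± 0.097), and NQM1 and TKL2 (a transaldolase and a transketolase, −4.02 ± 0.055 and −3.97 ± 0.082) completed the 12 largest falls together with SPS100, a spore wall gene (−4.36 ± 0.082).

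Proteasome, heat shock and chaperone, and autophagy genes fell with smaller medians. Of 36 proteasome genes 35 fell (35 adjusted over the list alone), with a median of −0.51, such as RPN5 (−0.98 ± 0.053), RPN11 (−0.98 ± 0.068) and SCL1 (−0.95 ± 0.066). RPN2, named after its value was seen, was the one that did not pass (0.04). Of 27 heat shock and chaperone genes 20 fell and 0 rose (20 adjusted over the list alone), with a median of −0.36 and HSP26 (−4.20), HSP30 (−4.12) and SSE2 (−1.89 ± 0.073) as the largest falls, and of 29 autophagy and vacuolar protease genes 20 fell and 1 rose (21 and 1 adjusted over the list alone, 0 rises without DMSO control replicate 1 and 2 without ebselen replicate 2), with a median of −0.44, for example ATG8 (−1.66 ± 0.12), ATG39 (−1.67 ± 0.090) and ATG41 (−1.66 ± 0.063). The limma camera adjusted p (Benjamini-Hochberg) was 2.41e-07, 0.00166 and 0.000987 for these lists, and adjusted p = 0.303, 0.267 and 0.296 with an estimated correlation.

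Genes of respiration and of carbon sources other than glucose fell too. Among 37 glucose-repressed genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation 32 fell and 2 rose (32 and 2 adjusted over the list alone), with a median of −0.98, for example MLS1 (malate synthase, −2.72 ± 0.070), POT1 (a thiolase of fatty acid oxidation, −2.69 ± 0.054) and CRC1 (a carnitine carrier, −2.19 ± 0.10). SUC2 (0.38) and ALD6 (0.33), named after their values were seen, were those that rose. Of 42 respiratory chain and ATP synthase genes 37 fell (38 adjusted over the list alone), with a median of −0.50, such as NDE2 (an external NADH dehydrogenase, −2.85 ± 0.051), and the ATP synthase regulators STF1 (−1.76 ± 0.054) and STF2 (−1.45 ± 0.082). Of 23 tricarboxylic acid cycle genes 19 fell and 2 rose (19 and 2 adjusted over the list alone, 0 rises without DMSO control replicate 2 and 1 without any other array), with a median of −0.43, among them CIT3 (a citrate synthase, −2.05 ± 0.054), FUM1 (fumarase, −1.24 ± 0.053) and SDH2 (−1.23 ± 0.053). These lists had limma camera adjusted p values (Benjamini-Hochberg) of 6.89e-07, 3.99e-07 and 0.000510, and adjusted p = 0.267 for each with an estimated correlation.

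Of 20 genes of glutamate metabolism 16 fell and 0 rose (16 adjusted over the list alone), with a median of −0.65. In limma's camera the list had an adjusted p (Benjamini-Hochberg) of 6.31e-05, and adjusted p = 0.267 with an estimated correlation. Among the glutamate dehydrogenases, GDH3 (YAL062W) fell 4.48-fold (−2.16 ± 0.053) and GDH2 (YDL215C), the glutamate-degrading enzyme, fell 1.73-fold (−0.79 ± 0.050). GDH1 (YOR375C) changed by −0.10 ± 0.056 and did not pass (limma adjusted p after Benjamini-Hochberg 0.163), although it passed as lower with centring on the S. pombe probe sets (0.0476) and with scaling on the hybridization controls (0.000122). UGA2 (−1.87 ± 0.091) and GAD1 (−1.85 ± 0.057), which degrade glutamate through 4-aminobutyrate, fell with GDH3.

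Further lists fell on balance with members in both directions. These were amino acid synthesis genes under Gcn4 (32 of 58 fell, 11 rose, median −0.25), thiamine and NAD synthesis (20 of 25 fell, 2 rose, median −0.38), meiosis and sporulation genes (20 of 34 fell, 3 rose, median −0.47), trehalose and glycogen genes (13 of 21 fell, 3 rose, median −0.57), nitrogen catabolite genes (18 of 30 fell, 5 rose, median −0.32), hexose transporters and sensors (14 of 22 fell, 3 rose, median −0.40) and glycolysis (10 of 22 fell, 1 rose, median −0.14). Adjusted over the list alone, 33 of the Gcn4 genes, 19 nitrogen catabolite genes and 8 glycolysis genes fell. Without DMSO control replicate 2, 6 Gcn4 genes rose, without DMSO control replicate 1, 3 nitrogen catabolite genes rose, and without either of these arrays 6 glycolysis genes fell. In the methods' t-test 6 Gcn4 genes rose and 10 sporulation genes fell. Examples were SNO1 and SNZ1, of vitamin B6 synthesis (−2.87 ± 0.077 and −2.84 ± 0.056), ARG3 (−2.56 ± 0.053), BNA2 (−1.91 ± 0.061), THI13 (−1.52 ± 0.054, on a probe set shared with related genes), PNC1 (−1.15 ± 0.050), SPS100 (above), DIT1 (−1.29 ± 0.062) and SPS22 (−1.14 ± 0.16). Others were GSY2 (−1.36 ± 0.056), GIP2 (−1.36 ± 0.085), ATH1 (−1.21 ± 0.083), UGA1 (−1.64 ± 0.054), PUT1 (−1.44 ± 0.070), GLN1 (−1.20 ± 0.067), HXT5 (−3.16 ± 0.11), MTH1 (−1.33 ± 0.13), MIG2 (−1.29 ± 0.074), PDC6 (−1.82 ± 0.066), GLK1 (−1.01 ± 0.075) and ADH5 (−0.95 ± 0.072). SPS22 lost its call in the methods' t-test (0.0731). All these examples fell, because the rule takes the direction of each list's median. Some members rose by as much or more. They were HXT2 of the hexose list (2.34) and, named after their values were seen, SPS4 of the sporulation list (1.63), GSY1 of the trehalose and glycogen list (1.42) and CAR1 of the nitrogen list (1.25). The limma camera adjusted p (Benjamini-Hochberg) was 0.0275 for the Gcn4, 0.00337 for the thiamine, 0.0222 for the sporulation, 0.0279 for the trehalose, 0.0316 for the nitrogen, 0.0373 for the hexose and 0.0470 for the glycolysis list, and adjusted p ranged from 0.267 to 0.514 with an estimated correlation. The trehalose and nitrogen lists lost their call without ebselen replicate 1 (0.0595 and 0.0927), the hexose list without DMSO control replicate 2 (0.0702), and glycolysis without either DMSO array (0.0781 and 0.0904) or ebselen replicate 1 (0.105). Glycolysis also missed the threshold with quantile normalization (0.0804), median centring (0.0758), the replicate number as a block (0.0514) and the trend over coding length removed (0.204), and its median lay at percentile 32.3 of random lists matched on length. With scaling on the hybridization controls the glycolysis (0.324), nitrogen (0.143), hexose (0.132) and trehalose (0.0598) lists missed it.

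**Figure D3:**
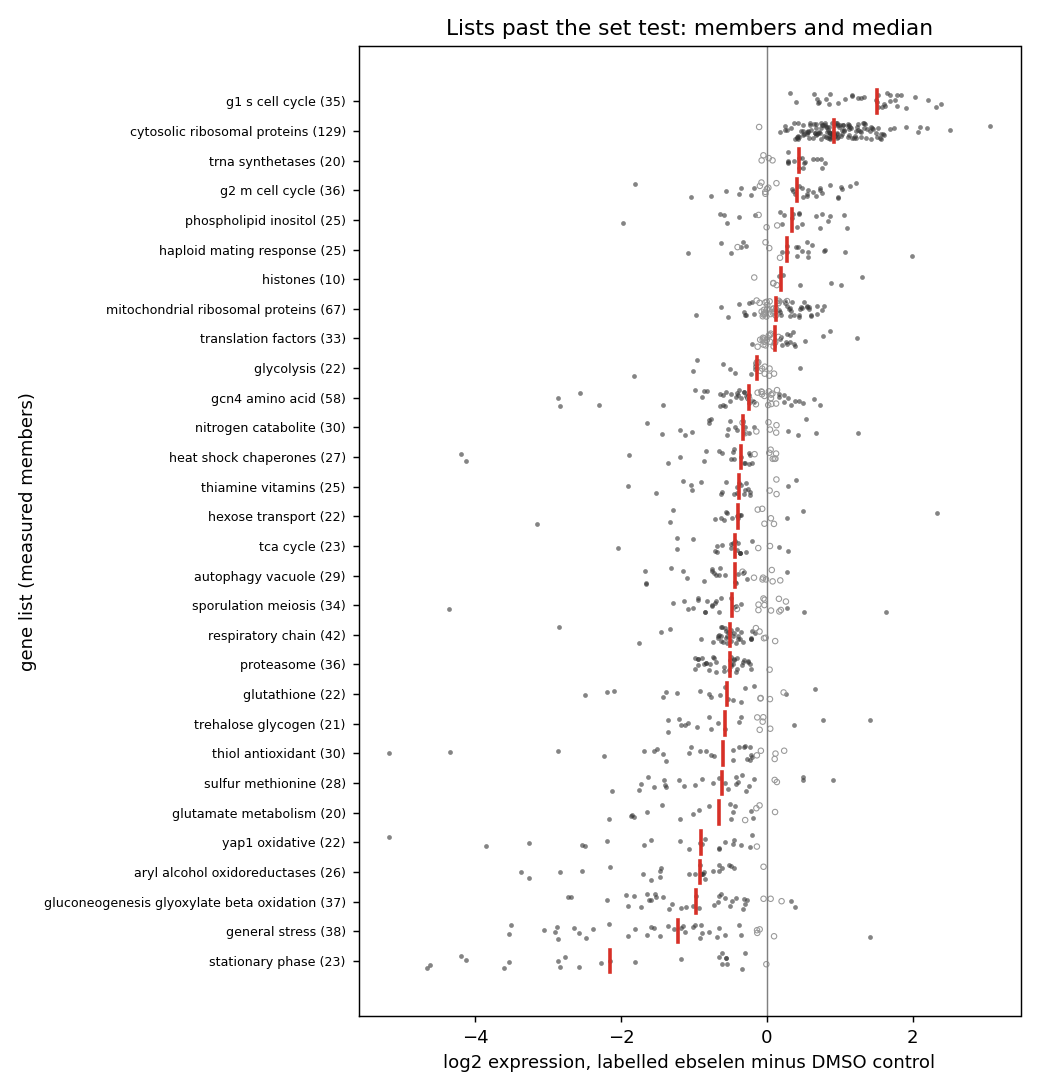
Log2 change (labelled ebselen minus DMSO control, horizontal axis) of the members of the 30 lists past the set test (vertical axis, with the number of measured members); filled points passed the gene test, open points did not, and red bars are medians. Medians run from −2.15 for stationary-phase markers to 1.52 for G1/S genes; with scaling on the hybridization controls 7 of the 9 positive medians, those other than G1/S and cytosolic ribosomal proteins, turn negative.

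Smaller rises were seen in 7 lists, whose medians all turned negative with scaling on the hybridization controls. They were aminoacyl-tRNA synthetases (16 of 20 rose, 0 fell, median 0.45, against −0.04 with that scaling), G2/M and M/G1 genes, called G2/M genes below (21 of 36 rose, 8 fell, median 0.41, against −0.08), phospholipid synthesis (16 of 25 rose, 6 fell, median 0.34, against −0.14), pheromone response and haploid genes (15 of 25 rose, 6 fell, median 0.28, against −0.20), histones (6 of 10 rose, 0 fell, median 0.20, against −0.29), mitochondrial ribosomal proteins (29 of 67 rose, 10 fell, median 0.13, against −0.36) and translation factors (15 of 33 rose, 1 fell, median 0.12, against −0.37). Counts changed with that scaling too: 1 synthetase rose and 4 fell, and G2/M genes had 7 and 15, phospholipid synthesis 4 and 10. Pheromone response genes had 3 and 10, histones 3 and 5, mitochondrial ribosomal proteins 1 and 38, and translation factors 2 and 19. Adjusted over the list alone, 5 histones and 14 translation factors rose. Without DMSO control replicate 1 or ebselen replicate 2, 6 mitochondrial ribosomal proteins fell, without ebselen replicate 1, 1 histone did, and without any 1 array 0 to 2 translation factors did. In the methods' t-test 7 translation factors rose. Examples were the leucyl-tRNA synthetase CDC60 (0.80 ± 0.056), GLN4 (0.75 ± 0.050), YHR020W (0.74 ± 0.059), the mitotic cyclin CLB2 (1.22 ± 0.064), CHS2 (1.14 ± 0.057), the replication helicase subunit MCM2 (1.03 ± 0.070), EPT1 (1.10 ± 0.050), PSD1 (1.06 ± 0.055) and CPT1 (0.87 ± 0.065). Others were the mating-type endonuclease HO (2.00 ± 0.081), FAR1 (1.07 ± 0.052), AGA1 (0.79 ± 0.057), the linker histone HHO1 (1.31 ± 0.075), HTB2 (1.01 ± 0.058), HTZ1 (0.87 ± 0.050), MRPL32 (0.79 ± 0.054), MRPL37 (0.75 ± 0.051), MRPL7 (0.69 ± 0.052), ANB1 (1.24 ± 0.17), the initiation factor TIF4631 (0.87 ± 0.050) and FUN12 (0.77 ± 0.056). ANB1 lost its call in the methods' t-test (0.0731), and GLN4, YHR020W, MRPL37, MRPL7 and FUN12 lost theirs with scaling on the hybridization controls (0.0609 to 0.190). The limma camera adjusted p (Benjamini-Hochberg) was 0.000207 for the synthetases and 0.0109 to 0.0419 for the others, and adjusted p ranged from 0.296 to 0.468 with an estimated correlation. With the trend over coding length removed, the G2/M and phospholipid lists missed the threshold (0.0693 and 0.101), and with all probe sets in one fit the pheromone list did (0.0590). With scaling on the hybridization controls the histone (0.0649), mitochondrial ribosomal protein (0.0758), pheromone (0.0758), translation factor (0.0834) and phospholipid (0.126) lists missed it.

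Among regulators fixed by name, YAP1 fell 2-fold (−1.0 ± 0.054), ZAP1, the zinc regulator, fell (−1.25 ± 0.066), and so did RPN4, the proteasome activator (−0.78 ± 0.062), and MSN4 (−0.77 ± 0.079). AFT1, the iron regulator, rose by 0.59 ± 0.11 and MSN2 by 0.37 ± 0.064, but neither passed the methods' t-test after Benjamini-Hochberg adjustment (0.102 and 0.0572), and with scaling on the hybridization controls AFT1 was at 0.11 and MSN2 at −0.12. MET4 fell (−0.27 ± 0.075, limma adjusted p after Benjamini-Hochberg 0.0228) and lost its call without either DMSO array or ebselen replicate 2 (0.0540 to 0.0768), with all probe sets in one fit (0.0725) and in the methods' t-test (0.133). HSF1 (−0.15 ± 0.061) and PDR1 (−0.04 ± 0.050) did not pass (0.0713 and 0.471), and both passed as lower with scaling on the hybridization controls and with the length trend removed (0.00360 and 0.00213), HSF1 also with centring on the S. pombe probe sets (0.0227).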

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

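Every test weighed here was chosen after the values were seen. Further signals lay in control and unnamed probe sets that the comparison of genes does not use.

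The first pattern is the direction of the response: stress and antioxidant genes lower, ribosomal protein and G1/S genes higher, in the arrays labelled ebselen. An exchange of 1 array between the groups is argued against by the spread: the largest SD of the difference between arrays of a group was 0.143, against at least 0.726 between groups, and a signal that depends on coding length is argued against because the medians of 4 of 4 lists (general stress, Yap1, ribosomal protein and G1/S) lay outside 10000 random lists matched on length. An exchange of the labels of both groups cannot be told apart from an effect of treatment: 21 of 22 Yap1 targets were lower, which an exchange may give if ebselen induces them as thiol oxidants do, and no other mark of treatment was tested for this. Glucose used up in the DMSO cultures cannot be told apart either, because its marks disagree. As depletion would give, 32 of 37 glucose-repressed genes were higher in DMSO, and 2 were lower. Contrary to depletion, 4 of 4 genes that high glucose induces were also higher in DMSO. Those 4 were chosen after their values were seen. A lowering of the stress, antioxidant and glucose-repressed genes by ebselen itself, and a difference in growth stage or density at harvest, stay open and were not tested.

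The second pattern is the lower 5′ signal, a mean change of −0.75 for 5′ minus 3′ over 8 yeast control transcripts in the arrays labelled ebselen. Shorter products of the labelling reaction are argued against by the poly-A spike-ins, whose mean change was 0.33, with the lowest spike-in (−0.07) above the highest yeast transcript (−0.35). Spike-in levels differed between the DMSO arrays (below). Without DMSO control replicate 2 the spike-ins changed by 0.75 (dap), 0.03 (lys), 0.03 (phe) and 0.69 (thr). Lower integrity of the RNA behind the arrays labelled ebselen is a candidate explanation: 8 of 8 transcripts fell at the 5′ end, and 6 of 8 had the middle probe set in between. Changed transcript starts or faster decay in treated cells were not tested and stay open.

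The poly-A spike-ins differed between the control arrays, with a median of 2.71 for DMSO control replicate 1 minus replicate 2, against −0.11 for ebselen replicate 1 minus replicate 2. The hybridization controls were higher in the arrays labelled ebselen by a median of 0.53. The 3517 probe sets with no listed gene were not assigned to a species. Of these, 103 passed with a change beyond the S. pombe 99th percentile, from −3.86 (1776865_at) to 2.10 (1777669_at). That fit held them together with the S. cerevisiae genes and the S. pombe probe sets. Of 1747 S. pombe probe sets, 265 passed when fitted together with the S. cerevisiae genes and 0 when fitted alone with limma (243 at an unadjusted p under 0.05), with a median change of 0.07.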

How the results depend on the processing

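With each array left out, quantile normalization, median centring, all probe sets in one fit, 1 probe set per gene, robust eBayes, S. pombe centring, removal of the length trend, thresholds of 0.01 and 0.1, and the methods' t-test, the totals of genes that rose and that fell stayed within 1.5 times their values. Counts within single lists moved further, for example from 20 sporulation genes lower to 10 in the methods' t-test. Genes called both as reported and in these settings kept their direction, except 18 with the length trend removed. Without 1 array, 1499 to 1777 genes rose and 1786 to 2108 fell, 9 to 10 lists rose and 18 to 21 fell; the lone array was assumed to vary like the other group. The methods' t-test after Benjamini-Hochberg adjustment called 1233 rises and 1410 falls, and its calls shared 2591 genes with those of limma. Replicate numbers did not pair the arrays (correlation of deviations −0.075, Spearman −0.088); with the replicate number as a block, 1670 genes rose and 1971 fell, and the glycolysis list missed the threshold (0.0514).

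Of the settings that moved counts by more than that, those on the S. pombe probe sets and the hybridization controls were chosen after seeing the data. Keeping only changes beyond the S. pombe 99th percentile left 685 rises and 962 falls, by construction. With scaling on the hybridization controls 414 genes rose and 3620 fell, 66 and 1138 by at least 2-fold, and camera placed 4 lists above the other genes, 2 of them with negative medians. That scaling shifts all genes together by construction. It reversed BAR1 (−0.0018), MSN2 (−0.12) and the medians of aminoacyl-tRNA synthetases (−0.039), G2/M genes (−0.076), phospholipid synthesis (−0.14), pheromone response genes (−0.20), histones (−0.29), mitochondrial ribosomal proteins (−0.36) and translation factors (−0.37). The medians of all 21 lists that fell kept their sign under every setting. With an estimated correlation, limma's camera had only the 2 residual degrees of freedom. It called 0 lists higher and 0 lower (2 and 6 at an unadjusted p under 0.05). Limma's fry called 13 higher and 27 lower. Signal over background is unknown in centred values, so how far dim probe sets limit small changes cannot be given.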

Other observations

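Iron uptake genes moved apart. FET3 (2.75 ± 0.050) and the siderophore transporter SIT1 (1.59 ± 0.051) rose, while the list as a whole had 8 of 29 members higher and 8 lower (8 and 8 adjusted over the list alone), with a median of −0.04 and a limma camera adjusted p after Benjamini-Hochberg of 0.676. Cell wall genes held the extremes PIR3 (a wall protein; −3.93 ± 0.085) and UTR2 (a chitin transglycosylase; 2.05 ± 0.061), with 10 of 37 higher and 17 lower (0.759). DNA damage genes had 12 of 30 higher and 13 lower (0.833), among them MSH6 (mismatch repair; 1.84 ± 0.055), which is also on the G1/S list. Among ribosome assembly genes 32 of 106 were higher and 34 lower (0.754, median 0.01), with ERB1 at 1.02 ± 0.070 and RRS1 at −1.02 ± 0.061. Subunits and factors of RNA polymerases I and III had 14 of 35 higher and 9 lower (0.173), with TFC4 at 0.83 ± 0.063 and RPC37 at −0.63 ± 0.10, which lost its call in the methods' t-test (0.0763). In that test 18 and 18 ribosome assembly genes, 6 and 3 polymerase genes, 4 iron genes lower and 11 cell wall genes lower passed.

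Endoplasmic reticulum chaperones had 14 of 26 members higher and 4 lower, with EUG1 (a protein disulfide isomerase) at 1.40 ± 0.063, MPD1 at 0.76 ± 0.083 and a limma camera adjusted p after Benjamini-Hochberg of 0.0824, which passed without ebselen replicate 2 (0.0332) and with the length trend removed (0.0442), and of which 5 members were higher in the methods' t-test. The pentose phosphate list had 4 of 18 higher and 11 lower (0.116), with NQM1 at −4.02 and TKL2 at −3.97. Ergosterol genes had 11 of 29 higher and 5 lower (0.138), with IDI1 at −0.73 ± 0.063 and ERG4 at 0.69 ± 0.055. Zinc genes had 4 of 20 higher and 11 lower (0.159), with MCD4 at 1.70 ± 0.059, and purine and pyrimidine genes 6 of 33 higher and 19 lower (0.165), with URA10 at −1.70 ± 0.050 and IMD2 at −1.91 ± 0.13 (on a probe set shared with related genes). Without DMSO control replicate 2, 11 of these were lower. Copper genes had 3 of 11 higher and 6 lower (0.274), with the metallothionein CRS5 at −1.09 ± 0.068 and CUP2 at −0.80 ± 0.068, and 1 was higher without DMSO control replicate 1 or ebselen replicate 1. Multidrug transport genes had 7 of 28 higher and 11 lower (0.665), with AQR1 at −1.51 ± 0.061 and TPO2 at −1.20 ± 0.066 (partly on a shared probe set). Phosphate genes had 8 of 21 higher and 9 lower (0.977), with GPP2 at −1.57 ± 0.051 and PHM8 at −1.49 ± 0.051. Markers of MATa cells had 2 of 7 higher and 2 lower, and those of MAT alpha cells 1 of 5 higher and 2 lower (0.754 for each), with STE3 at −1.11 ± 0.086, AFB1 at 0.73 ± 0.070, STE6 at 0.67 ± 0.064 and BAR1 at 0.48 ± 0.086, which lost its call in the methods' t-test (0.0830). With all probe sets in one fit the pentose phosphate (0.00796), zinc (0.0214) and purine and pyrimidine (0.0139) lists passed as lower, and the multidrug list did with the length trend removed (0.0442). The pentose phosphate list also passed with scaling on the hybridization controls (6.95e-05), where ERG4, STE6, AFB1, MPD1 and BAR1 lost their calls (0.198, 0.227, 0.121, 0.0758 and 0.992), BAR1 at −0.0018. With scaling on the hybridization controls, where the median of all genes was −0.52, fewer members of each of these lists were higher and more were lower. The iron list had 3 higher and 20 lower, cell wall 6 and 27, DNA damage 9 and 18, ribosome assembly 3 and 70, the polymerases 1 and 21, and endoplasmic reticulum chaperones 1 and 11. Pentose phosphate had 0 and 14, ergosterol 0 and 18, zinc 1 and 16, purines and pyrimidines 1 and 28, copper 0 and 9, multidrug 1 and 21, phosphate 2 and 13, MATa markers 0 and 5, and MAT alpha markers 0 and 4.

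Genes that high glucose induces, chosen after their values were seen, were lower in the arrays labelled ebselen: HXT1 (−0.37 ± 0.050), HXT3 (−0.63 ± 0.059), MIG2 (−1.29 ± 0.074) and MIG3 (−0.59 ± 0.075), in all 15 settings tried. Changes tended to be higher in genes with long coding regions (Spearman 0.194 over 5449 genes, which are not independent replicates), but not steadily. From the shortest to the longest of 5 equal classes the medians were −0.08, −0.19, −0.13, −0.03 and 0.21.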
